A study of Mus musculus with 4 samples.

How the data were processed

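Total RNA was extracted with TRIzol from mouse EpSC cultures treated for 48 h, and a service company prepared the libraries, per the labels' protocols. The library kit, its strandedness and the sequencing layout are not given in the sources used here, so reads of a gene and of an antisense partner cannot be told apart. The authors deposited 1 table with, for 54532 mouse Ensembl genes, a raw count per library and the columns of their own comparison. Reads were aligned with HISAT2 2.0.5 and counted with featureCounts 1.5.0-p3, per the submitters' processing notes. Those notes name the human build GRCh38, whereas every gene identifier in the table is a mouse one. Of these identifiers 54495 (99.9%) occur in GENCODE M21, and 98.3% of the matched genes have the same chromosome, start and end as in that GRCm38 annotation, so coordinates are given as GRCm38. How reads with several best positions were counted is not given in the sources used here.

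The deposited counts are whole numbers, not normalized, with totals between 15766244 and 17430345 per library. The table also holds 4 FPKM columns, 1 per library, which were not used here. The normalized signal columns of the authors' deposited table, 1 mean per group, equal the group means of counts divided by median-of-ratios size factors. The log2 fold changes and p-values in the authors' deposited table come from a test that is not given in the sources used here. For the named genes they nearly match DESeq2's Wald test run here. Cxcl1 has 5.29 in both, with adjusted p-values of 4.01e-38 and 4.18e-38, so the 2 are not separate lines of evidence. The authors' adjusted p-values equal the Benjamini-Hochberg adjustment over genes with a normalized mean above about 11.5, and are exactly 1 for 9265 genes below it. Of the rows, 0 named no gene. In 27 rows a symbol had been turned into a date, and these were restored by gene identifier.

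The table's columns carry replicate numbers that differ from those in the labels, so each column was assigned to its group and not to a single labelled sample. In each group the column numbers, which run up to 3, leave out a number. Whether further libraries were made is not given in the sources used here. The letters A and B follow the order of the columns, pair nothing and are names only. Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, libraries were scaled by TMM, and ALP was compared with control by the quasi-likelihood F test (glmQLFit and glmQLFTest, two-sided) in a model with the group alone. P-values were adjusted by Benjamini-Hochberg, and a gene was called at an adjusted p under 0.05. The fit had 2 residual degrees of freedom, a median prior of 3.53 degrees of freedom and a common biological coefficient of variation of 0.144. CPM values are TMM-scaled, and 3 counts correspond to between 0.172 and 0.19 CPM before scaling. Counts of reads without molecular identifiers are not independent molecules, so counting error is a lower limit on the error of a level.

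The 31 gene lists, the tests, the naming rule and all alternatives of the fit but 1 were fixed before the data were examined. The lists cover basal and stem keratinocytes, keratinocyte differentiation, wound and stress keratins, G1/S and DNA replication, G2/M and mitosis, G1 cyclins and inhibitors, Wnt targets, Wnt ligands, receptors and transducers, Notch, TGF-beta and BMP targets, EGFR ligands and MAPK feedback, YAP/TEAD targets, interferon response, NF-kB and inflammation, p53 targets, unfolded protein and amino acid stress, NRF2, cholesterol synthesis, fatty acid synthesis, glycolysis and hypoxia, mitochondrial mRNAs, cytosolic ribosomal proteins, MYC targets and ribosome biogenesis, extracellular matrix, 6 other cell types and sex-linked transcripts. Lists with at least 5 tested members were compared with all other genes by camera (limma 3.58.1, voom weights, preset correlation 0.01, two-sided) and adjusted over the 29 lists tested. Camera was repeated with an estimated correlation. Fry's directional test asks whether the genes of a list move, on balance, one way, and compares them with no other genes. Standard errors are the log2 fold change divided by the square root of the quasi-likelihood F statistic.

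Named genes were chosen by 4 rules. The first took, among called protein-coding genes with a mean of at least 5 CPM in the higher group and no overlap between the groups' libraries, the 7 largest increases and the 7 largest decreases, from 2325 and 1477 eligible genes. The second took the 4 increases and 4 decreases with the smallest p-values beyond these. The third took up to 4 members of each list with the smallest p-values. The fourth took Mki67, Ccnd1, Myc, Cdkn1a, Krt14, Krt10, Axin2 and Ctnnb1 whatever their result. Krt1, Ivl, Erbb3, S100a8, S100a9, Mmp2, Smad6, Id3, Id4 and Xist are named outside these rules and were chosen after their values were seen. The same holds in the closing section for the transcription factors and for Cdh5, Cldn5, Emcn, Esam, Tie1 and Vwf of the endothelial list. A few genes that these rules name are not reported here.

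Alternatives were DESeq2 1.42.0 size factors, upper-quartile scaling and library totals in the same fit, no low-count filter, at least 10 CPM in 2 libraries, DESeq2's Wald test, limma-voom, an adjusted p under 0.01, protein-coding genes alone, each library left out in turn, and edgeR's earlier quasi-likelihood method, the last added after seeing the data. With 1 library left in a group, that library was assumed to vary like the other group. The fit was tested on simulated counts of 13791 genes for ALP against control, drawn from the real means, library sizes and trended dispersions, with 200 genes changed. It recovered 12.2% of genes changed 1.5-fold, 69.4% of those changed 2-fold, 98% at 4-fold and 100% at 8-fold, each with the right sign, and called 6 unchanged genes. Where 4281 genes changed 2-fold, 81.4% were called and 3.28% of the calls were unchanged genes. In both simulations genes were drawn independently, with the same dispersion in both groups and no scatter around the trend. The real ALP pair differed more than the control pair, so these rates may not hold for the real libraries. In a simulation with 1 list shifted 1.5-fold, camera called it and 0 of 28 unshifted lists. Its genes were drawn independently, so it does not test camera on lists whose members vary together. In the real libraries the estimated correlation was 0.646 for G1/S and DNA replication and 0.744 for MYC targets and ribosome biogenesis. Figures were drawn with matplotlib, and exon overlaps and transcript sequences came from GENCODE M21.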

Results

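RNA sequencing was performed on epidermal stem cells (EpSCs), the keratinocyte progenitors that renew the epidermis, isolated from the skin of C57BL/6 mice and grown in EpiLife medium with growth supplement. Cultures received 30 μg/mL ALP, read here as the Arctium lappa L. (burdock) polysaccharide named in the series title, or 0.06% DMSO as the vehicle control, for 48 h. Each group held 2 libraries, with total gene counts of 17430345 for ALP replicate A, 15766244 for ALP replicate B, 17415047 for control replicate A and 17360445 for control replicate B. The letters A and B only name the libraries. The labels do not say whether the libraries of a group came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical. They also do not say whether the ALP cultures received DMSO.

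All 4 libraries differed from each other by more than counting noise. The chi-square per degree of freedom was 6.42 for the control pair, 24.8 for the ALP pair and between 59.8 and 164 for the 4 pairs across groups. The first principal component took 85.8% of the variance and placed ALP replicate A at -21.6, ALP replicate B at -76.9, control replicate A at 55.8 and control replicate B at 42.7. Transcripts of the mitochondrial genome took 1.73% and 1.71% of the counts in the ALP libraries against 2.29% and 2.12% in the controls.

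The single comparison of the design, ALP against control, asks which transcripts change under a treatment that the series title links to proliferation. After ALP, 39 of 40 genes of the G1/S transition and DNA replication, 27 of 30 of ribosome biogenesis and MYC targets and 19 of 24 of cholesterol synthesis rose, while 15 of 35 keratinocyte differentiation genes fell. The median log2 difference of the differentiation list from the control mean was -1.15 in ALP replicate A and -2.27 in ALP replicate B. With an estimated correlation between genes none of these 4 lists passed, with an adjusted p = 0.572 for the first 3 and an adjusted p = 0.598 for differentiation. That version had little power, since the 4 libraries leave 2 residual degrees of freedom to estimate the correlation. The preset correlation of 0.01 in turn gives p-values that are too small if members vary together as estimated (0.646, 0.744, 0.626 and 0.642). Fry, which presets no correlation, passed none of the 4 either (adjusted p = 0.0797 for the first 3 and 0.13 for differentiation). Il24, which encodes a cytokine of the IL-10 family, rose by 6.05 ± 0.42 on the log2 scale (SE, n = 2 per group), from 0.370 ± 0.042 to 24.9 ± 9.25 CPM (mean ± SD; counts per 1000000, TMM-scaled). Ccnd1, which encodes cyclin D1, rose by 2.39 ± 0.22, from 66.3 ± 9.09 to 347 ± 99.5 CPM. Scel, which encodes sciellin, a precursor of the cornified envelope, fell by 3.96 ± 0.60, from 12.8 ± 1.37 to 0.788 ± 0.931 CPM. Its log2 difference was -6.55 without ALP replicate A. Of 14056 genes tested, 4350 changed at an adjusted p under 0.05 by edgeR's quasi-likelihood test, 2537 of them higher and 1813 lower in ALP.

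Among the changed genes, 1556 changed at least 2-fold, 812 upward and 744 downward. In all 4350 changed genes both ALP libraries lay on one side of both controls. This held for 10641 of all tested genes (75.7%), against 33.3% expected by chance for a single gene with 2 against 2 libraries. Genes vary together and the calls rest on the same 4 libraries, so neither count adds support to the calls. Protein-coding genes made up 4140 of the changed genes, with 2461 higher and 1679 lower. All the adjusted p-values of the calls lay between 0.0149 and 0.05, and with either control library left out edgeR called 0 genes, although 3380 genes without control replicate A and 4131 without control replicate B had an unadjusted p under 0.05 (6552 with all libraries). No gene was called by edgeR without the low-count filter or at an adjusted p under 0.01. DESeq2's Wald test, with its own default filter on mean counts, called 4056 genes, and limma-voom, with the low-count filter, called 4741.

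**Figure D1:**
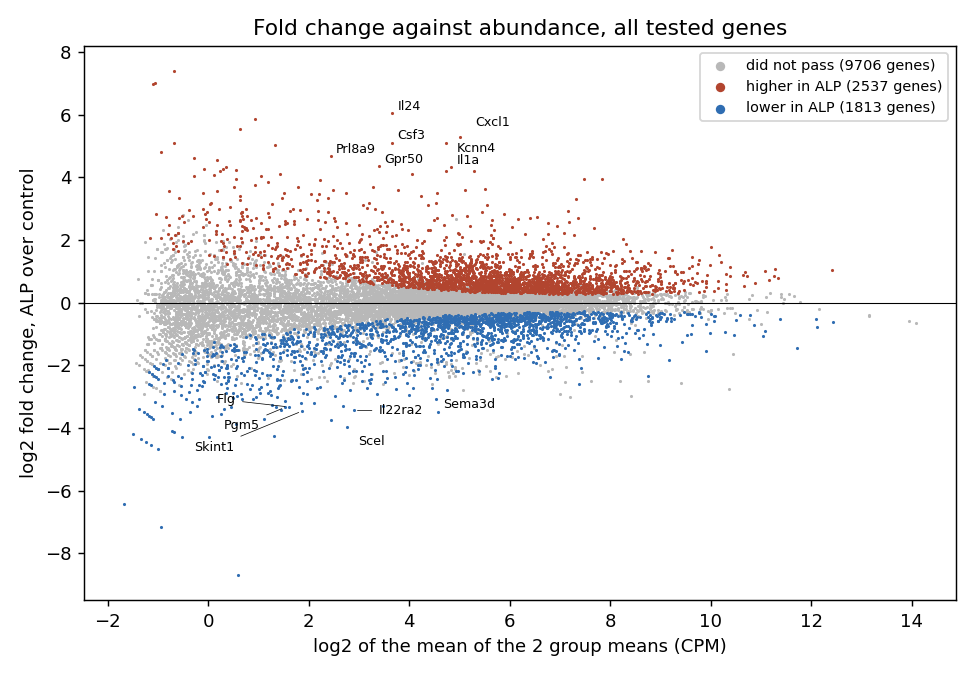
Each point is 1 of the 14056 tested genes, with the log2 of its mean abundance in CPM on the horizontal axis and its log2 fold change, ALP over control, on the vertical axis. The 2537 genes higher in ALP and the 1813 lower are coloured, and the labelled genes are among the 7 largest changes each way of called protein-coding genes with a mean of at least 5 CPM in the higher group.

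Of the 7 largest increases, 4 were in genes of secreted immune mediators. Besides Il24 (chromosome 1, 130882074 to 130887454, GRCm38), Cxcl1, a neutrophil chemoattractant on chromosome 5 (90891241 to 90893115), rose by 5.28 ± 0.46 to 63.4 ± 31.2 CPM. Csf3, which encodes granulocyte colony-stimulating factor, rose by 5.10 ± 0.68, and Il1a, which encodes interleukin-1 alpha, rose by 4.33 ± 0.48. The other genes of this group were Kcnn4, encoding a calcium-activated potassium channel, at 5.09 ± 0.48, Prl8a9 of the prolactin family at 4.68 ± 0.74 and the orphan receptor gene Gpr50 at 4.36 ± 0.35. Their adjusted p-values were 0.0149 for each gene except Prl8a9, at 0.0155. Several of these folds depend on the control library. Without control replicate A and without control replicate B, Csf3 rose by 4.41 and 6.41, Prl8a9 by 3.90 and 6.44 and Kcnn4 by 4.52 and 6.02. In the same fits Il1a rose by 3.82 and 5.10, Cxcl1 by 4.97 and 5.66, Gpr50 by 4.19 and 4.55 and Il24 by 5.92 and 6.17. Prl8a9 belongs to a family of close paralogs, and its count is uncertain where reads fit several members. The increases with the smallest p-values beyond these were those of Hmga2, a chromatin protein gene of stem and fetal cells, by 3.94 ± 0.28 to 337 ± 126 CPM, Dusp6 by 4.19 ± 0.31, Etv4 by 4.21 ± 0.33 and Tgfa by 2.72 ± 0.21.

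The largest decreases fell on genes of the upper epidermis and on several of low abundance. Next to Scel (chromosome 14, 103513342 to 103612797), Flg, which encodes filaggrin, fell by 3.33 ± 0.57 (adjusted p = 0.0171), and Skint1, a gene expressed by keratinocytes and thymic epithelium, fell by 3.46 ± 0.70 (adjusted p = 0.0225). Il22ra2, which encodes the soluble inhibitor of interleukin-22, fell by 3.44 ± 0.85 and had 0 counts in ALP replicate B. Sema3d, a semaphorin gene, fell by 3.48 ± 0.87 and measured 7.29 and 0.388 CPM in the ALP libraries against 50.1 and 37.5 in the controls. Pgm5 fell by 3.34 ± 0.47. By DESeq2's Wald test, Sema3d (adjusted p = 0.0786), Skint1 (adjusted p = 0.0597) and Il22ra2 (adjusted p = 0.332) did not pass. Without ALP replicate A the fitted decreases were larger, at -6.80 for Sema3d, -6.55 for Skint1 and -5.35 for Flg. For Il22ra2, with 0 counts in the library left, the fit gives no bound. The decreases with the smallest p-values were smaller and even between libraries. Serpina3g fell by 1.56 ± 0.11, Arrdc4 by 1.33 ± 0.10, the collagenase gene Mmp13 by 2.01 ± 0.15 and Fam129a by 1.52 ± 0.13. Serpina3g is one of a cluster of closely related genes, and its count is uncertain for that reason.

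**Figure D2:**
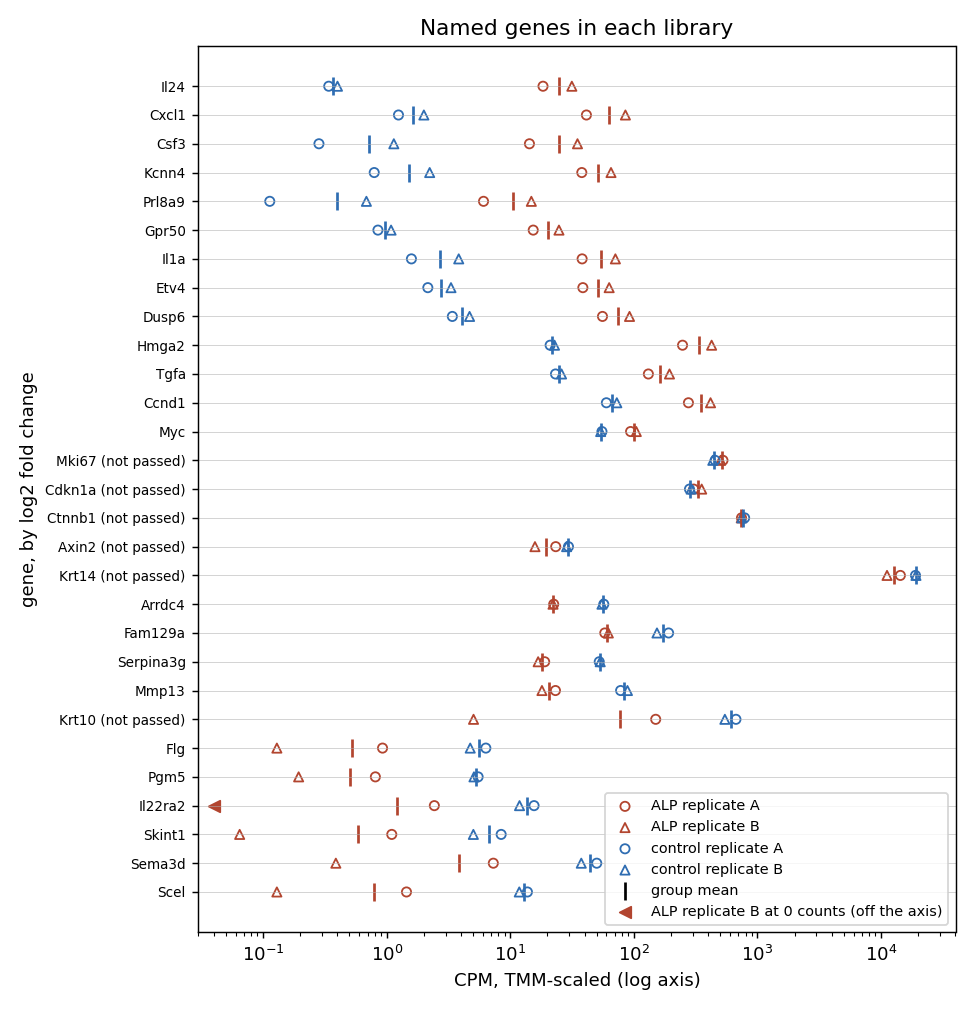
Abundance of each named gene in the 4 libraries, in TMM-scaled CPM on a log axis, with circles for replicate A, triangles for replicate B, red for ALP, blue for control and vertical ticks for group means. Krt10 measured 150 and 5.04 CPM in the ALP libraries, and an arrowhead at the left edge marks Il22ra2, which had 0 counts in ALP replicate B.

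Among 31 gene lists fixed before the data were examined, 29 had at least 5 tested members and 15 of these moved by limma's camera test with a preset correlation of 0.01, 9 of them up and 6 down. With a correlation estimated from the 4 libraries, 0 of the 29 lists passed, and the smallest adjusted p was 0.572. Only 2 residual degrees of freedom support that estimate, and the smallest unadjusted camera p was 0.105, for G2/M and mitosis. A list that fails this version is therefore not shown to be unmoved, and the version cannot decide between lists. The preset version gives p-values that are too small where the members of a list vary together. The self-contained test fry called 1 list. In a fit without 1 library, the spread comes from the other group alone. Without an ALP library that is the control pair, which differed less than the ALP pair. Larger counts in such fits leave out the spread between the ALP libraries and are not added support. The counts of members below come from the gene-wise test, over all genes tested unless stated, and all of them are 0 without either control library.

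The replication genes rose almost without exception. Of 40 tested members of the list for the G1/S transition and DNA replication, 39 rose and 0 fell, with the same numbers adjusted over the list alone and 1 down without ALP replicate A, and the median log2 fold change was 1.13 (camera adjusted p = 8.60e-17, adjusted p = 0.572 with an estimated correlation). Mcm3, Mcm2 and Mcm4, which encode subunits of the replicative helicase, rose by 1.65 ± 0.14, 1.21 ± 0.11 and 1.22 ± 0.11, and Uhrf1, which is needed to maintain DNA methylation through replication, rose by 1.53 ± 0.15. Genes of G2/M and mitosis rose by less, with 28 of 40 higher, 0 lower and 33 higher when adjusted over the list alone, and 2 lower without ALP replicate A (median 0.46, camera adjusted p = 1.61e-09, adjusted p = 0.572 with an estimated correlation). Cdk1, the mitotic kinase gene, rose by 0.83 ± 0.10 and Ube2c by 0.74 ± 0.10. Kif20a rose by 0.61 ± 0.09, but 29.3% of its exon bases overlap exons of Cdc23 on the opposite strand. Mki67, the proliferation marker, measured 515 ± 15.6 CPM in ALP and 445 ± 13.5 in control, a log2 difference of 0.21 ± 0.08 that did not pass (adjusted p = 0.105). That difference was 0.17 without ALP replicate A and 0.25 without ALP replicate B.

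Of 17 G1 cyclins and cell cycle inhibitors, 7 rose and 2 fell (7 and 3 adjusted over the list alone, 8 and 4 without ALP replicate A), and the list did not pass (camera adjusted p = 0.177). Besides Ccnd1, Myc rose by 0.87 ± 0.10, the cyclin D2 gene Ccnd2 by 0.72 ± 0.12 and Rbl1, of the retinoblastoma family, by 0.49 ± 0.09. Ccnd1 shares 23.4% of its exon bases with a gene on the opposite strand that had 1157 counts over the 4 libraries against 13557 for Ccnd1. The inhibitor gene Cdkn1a measured 329 ± 34.6 CPM in ALP and 286 ± 6.16 in control and did not pass (log2 difference 0.20 ± 0.10, adjusted p = 0.171). That difference was 0.30 without ALP replicate A and 0.10 without ALP replicate B.

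Genes of ribosome biogenesis and MYC targets rose while mRNAs of the ribosomal proteins themselves fell. In the first list 27 of 30 members rose and 0 fell (29 and 0 adjusted over the list alone), with a median of 0.89 (camera adjusted p = 1.81e-12, adjusted p = 0.572 with an estimated correlation). Its members with the smallest p-values were Tfrc, the transferrin receptor gene, up by 1.77 ± 0.14, Cad, of pyrimidine synthesis, up by 1.58 ± 0.15, Srm, the spermidine synthase gene, up by 1.38 ± 0.15, and Rrp12, of ribosomal RNA processing, up by 1.01 ± 0.11. Of 41 cytosolic ribosomal protein genes, 27 fell and 0 rose (35 and 0 adjusted over the list alone), and the median was -0.34 (camera adjusted p = 4.28e-11, adjusted p = 0.572 with an estimated correlation). Rps27 fell by 0.87 ± 0.14 and Rps18 by 0.52 ± 0.09. Ribosomal protein genes have many processed pseudogenes, and reads that fit both are uncertain. The mitochondrially encoded mRNAs were also lower, with 5 of 12 down and 0 up by either adjustment, over all genes and adjusted over the list alone (median -0.37, camera adjusted p = 0.0014, adjusted p = 0.604 with an estimated correlation). Among them mt-Nd6 fell by 0.75 ± 0.10 and mt-Nd5 by 0.56 ± 0.11, and as adjacent genes on opposite strands they overlap at their ends.

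Lipid synthesis genes rose together. Of 24 cholesterol synthesis genes, 19 rose and 0 fell (22 and 0 adjusted over the list alone, 21 and 1 without ALP replicate A), with a median of 0.96 (camera adjusted p = 1.61e-09, adjusted p = 0.572 with an estimated correlation). Dhcr7, which encodes the last enzyme of the pathway, rose by 1.77 ± 0.18, Insig1 by 1.54 ± 0.15 and Hsd17b7 by 1.38 ± 0.16. Of 19 genes of fatty acid synthesis and lipid storage, 12 rose and 0 fell (12 and 1 adjusted over the list alone, 12 and 2 without ALP replicate A), with a median of 0.48 (camera adjusted p = 0.000193, adjusted p = 0.572 with an estimated correlation). Fasn, the fatty acid synthase gene, rose by 1.35 ± 0.14 to 1248 ± 150 CPM, Elovl6 by 1.28 ± 0.18 and Acly by 0.97 ± 0.13, and Fads1 rose from 44.1 ± 8.95 to 124 ± 22.5 CPM.

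EGFR ligands and feedback genes of MAPK signalling rose, with 18 of 26 members up and 1 down, or 18 and 2 adjusted over the list alone and 18 and 3 without ALP replicate A, and a median of 1.58 in ALP replicate A and 2.07 in ALP replicate B against the control mean (camera adjusted p = 0.000193, adjusted p = 0.572 with an estimated correlation). Spry4, a feedback inhibitor gene, rose by 5.04 ± 0.42 at low abundance, from 0.142 ± 0.041 to 4.91 ± 0.731 CPM. The phosphatase gene Dusp6, the ETS factor gene Etv4 and the ligand gene Tgfa belong to this list, and the member that fell was Erbb3. In the NF-kB and inflammatory list 18 of 30 members rose and 2 fell (20 and 2 adjusted over the list alone, 20 and 6 without ALP replicate A). The median was 1.03 (camera adjusted p = 0.000531, adjusted p = 0.572 with an estimated correlation). Over the 19 members with at least 10 CPM in 2 libraries the median was 0.46. The leading members of the list were Il24, Cxcl1, Il1a and Csf3, while S100a8 and S100a9, which encode the subunits of calprotectin, fell by 1.32 and 1.41. The interferon response list did not pass, with 2 of 27 members up and 3 down by either adjustment, adjusted over the list alone included (camera adjusted p = 0.35). These counts were 4 and 9 without ALP replicate A. Ddx58, which encodes the RNA sensor RIG-I, rose from 33.3 ± 4.06 to 66.9 ± 9.35 CPM and Irf1 rose by 0.88 ± 0.18, whereas Irf9 fell by 1.36 ± 0.17 and Ifi27 by 1.76 ± 0.27.

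In the NRF2 and antioxidant list 15 of 26 genes rose and 3 fell (16 and 3 adjusted over the list alone), with a median of 0.49 (camera adjusted p = 0.00098, adjusted p = 0.598 with an estimated correlation). Nqo1, a quinone reductase gene, rose by 1.86 ± 0.16, Txnrd1 by 1.63 ± 0.18, Gsr by 1.53 ± 0.16 and Pgd by 1.09 ± 0.13. In the list of extracellular matrix and mesenchymal transition 10 of 19 rose and 1 fell (10 and 2 adjusted over the list alone, and 2 down without either ALP library), with a median of 0.91, or 0.60 without control replicate A (camera adjusted p = 0.00175, adjusted p = 0.64 with an estimated correlation). Thbs1 rose by 1.54 ± 0.22 to 1714 ± 279 CPM, Col4a1 by 1.17 ± 0.18, Tnc by 1.14 ± 0.17 and Timp1 by 2.93 ± 0.35, and Mmp2 fell by 1.55.

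Keratinocyte differentiation genes fell, and the ALP libraries differed in how far. Of 35 tested members 15 fell and 1, the involucrin gene Ivl, rose by 0.92, and adjusted over the list alone 25 fell and 1 rose. Over all genes 25 fell by limma-voom. The median was -1.69 (camera adjusted p = 1.79e-08, adjusted p = 0.598 with an estimated correlation), with a median of -1.15 in ALP replicate A and -2.27 in ALP replicate B against the control mean. The loricrin gene Lor fell by 2.55 ± 0.25, Cdsn, the corneodesmosin gene, by 2.05 ± 0.24, Sprr1a by 1.94 ± 0.23 and Lce1a1 by 2.91 ± 0.45. The Sprr and Lce genes are families of close paralogs, and their counts are uncertain. Krt10, the suprabasal keratin, measured 150 and 5.04 CPM in the ALP libraries against 669 and 545 in the controls and did not pass in edgeR (log2 difference -2.97 ± 1.28, adjusted p = 0.125). It passed by limma-voom (adjusted p = 0.0423). In edgeR it passed without ALP replicate A (log2 difference -6.91, adjusted p = 6.96e-10) and without ALP replicate B (adjusted p = 2.30e-09). Its partner Krt1 measured 663 and 19.7 CPM against 2511 and 2086 (adjusted p = 0.164).

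Basal and stem cell genes went both ways. Of 25 members 10 rose and 6 fell (10 and 8 adjusted over the list alone, and 10 and 10 by limma-voom and without either ALP library). The median was -0.04 and the mean 0.06 (camera adjusted p = 0.965, direction up). In other settings the median lay between -0.12 with at least 10 CPM in 2 libraries and 0.01 without control replicate B. Itga3 rose by 1.78 ± 0.20 to 1588 ± 349 CPM, Itgb4 by 1.14 ± 0.15 and Cd44 by 1.17 ± 0.14, and the hair follicle stem cell gene Lgr5 fell by 2.18 ± 0.33. Krt14, the basal keratin, measured 14324 and 11170 CPM in ALP against 18985 and 19150 in control and did not pass in edgeR (log2 difference -0.58 ± 0.22, adjusted p = 0.0982). It passed by DESeq2's Wald test (adjusted p = 0.00076) and by limma-voom (adjusted p = 0.0254). In edgeR the log2 difference of Krt14 was -0.78 without ALP replicate A and -0.40 without ALP replicate B. Of 14 wound and stress keratin list members 7 rose and 3 fell (7 and 5 adjusted over the list alone, camera adjusted p = 0.58). The number that fell was 6 without ALP replicate A and 5 without ALP replicate B and by limma-voom. Krt18 was up by 3.69 ± 0.38, Mmp9 by 3.31 ± 0.36, Plaur by 3.13 ± 0.32 and Mmp13 down.

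Wnt genes showed no common rise. The list of Wnt ligands, receptors and transducers had 2 of 33 members up and 3 down, or 1 and 2 adjusted over the list alone (median -0.23, camera adjusted p = 0.0459, adjusted p = 0.64 with an estimated correlation). The number that fell was 7 by DESeq2's Wald test, 8 by limma-voom, 15 without ALP replicate A and 10 without ALP replicate B. The list's median was -0.10 in ALP replicate A and -0.26 in ALP replicate B, and -0.11 without ALP replicate B. Without control replicate B the list did not pass (camera adjusted p = 0.129). Wnt7a rose by 2.19 ± 0.27 and Wnt9a by 0.87 ± 0.23 (0.57 without control replicate A), whereas the receptor genes Fzd1 and Fzd6 fell by 1.12 ± 0.21 and 0.75 ± 0.13. Of 17 Wnt target genes 4 rose and 2 fell (6 and 6 adjusted over the list alone, camera adjusted p = 0.843). These counts were 6 and 8 without ALP replicate A, 5 and 5 without ALP replicate B, and 4 and 5 by DESeq2's Wald test and by limma-voom. Those that rose were Ccnd1, Myc, Cd44 and Ephb2, the last by 1.67 ± 0.24. Axin2, a feedback target of the pathway, measured 19.6 ± 5.29 CPM in ALP and 29.1 ± 0.708 in control and did not pass (log2 difference -0.57 ± 0.20, adjusted p = 0.0784). That difference was -0.88 without ALP replicate A and -0.31 without ALP replicate B. Ctnnb1, the beta-catenin gene, measured 741 ± 2.24 and 767 ± 27.8 CPM (adjusted p = 0.684).

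Other pathway lists did not pass. Of 17 TGF-beta and BMP targets 5 rose and 6 fell (6 and 7 adjusted over the list alone, 6 and 10 without ALP replicate A, camera adjusted p = 0.564). The direction was down in camera, with a median of -0.74, and up in fry (adjusted p = 0.944). That median was -0.30 in ALP replicate A and -1.42 in ALP replicate B, and it was -0.23 without ALP replicate B, -1.18 without ALP replicate A and 0.17 over the 12 members with at least 10 CPM in 2 libraries. Fn1 rose by 1.42 ± 0.22 and Pmepa1 by 0.61 ± 0.13, whereas the BMP-responsive genes Smad6, Id3 and Id4 fell by 1.97, 1.54 and 2.11. Of 17 YAP/TEAD targets 6 rose and 3 fell by either adjustment, adjusted over the list alone included (camera adjusted p = 0.177), led by Ctgf at 2.68 ± 0.28 and Cyr61 at 2.05 ± 0.27. Without control replicate B the YAP/TEAD list passed (camera adjusted p = 0.0405). Of 12 Notch pathway genes 1 rose, Jag1 by 0.55 ± 0.13, and 0 fell (2 and 4 adjusted over the list alone, camera adjusted p = 0.177). In this list 2 members fell by DESeq2's Wald test and by limma-voom, 7 without ALP replicate A, with 2 up, and 3 without ALP replicate B. Of 24 p53 targets 7 rose and 5 fell (10 and 7 adjusted over the list alone, 12 and 9 without ALP replicate A, camera adjusted p = 0.406), with Plk3 up by 2.22 ± 0.25. Of 30 genes of the unfolded protein and amino acid stress response 10 rose and 9 fell (10 and 10 adjusted over the list alone, camera adjusted p = 0.965). The chaperone gene Hyou1 rose by 0.99 ± 0.15 and Manf by 1.14 ± 0.17, while Trib3 and Atf5 of the amino acid response fell by 1.05 ± 0.11 and 1.22 ± 0.16. Of 29 glycolysis and hypoxia genes 5 rose and 6 fell (5 and 8 adjusted over the list alone, 5 and 14 without ALP replicate A, 6 and 11 without ALP replicate B). The camera adjusted p was 0.198, and 0.022 without ALP replicate A.

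**Figure D3:**
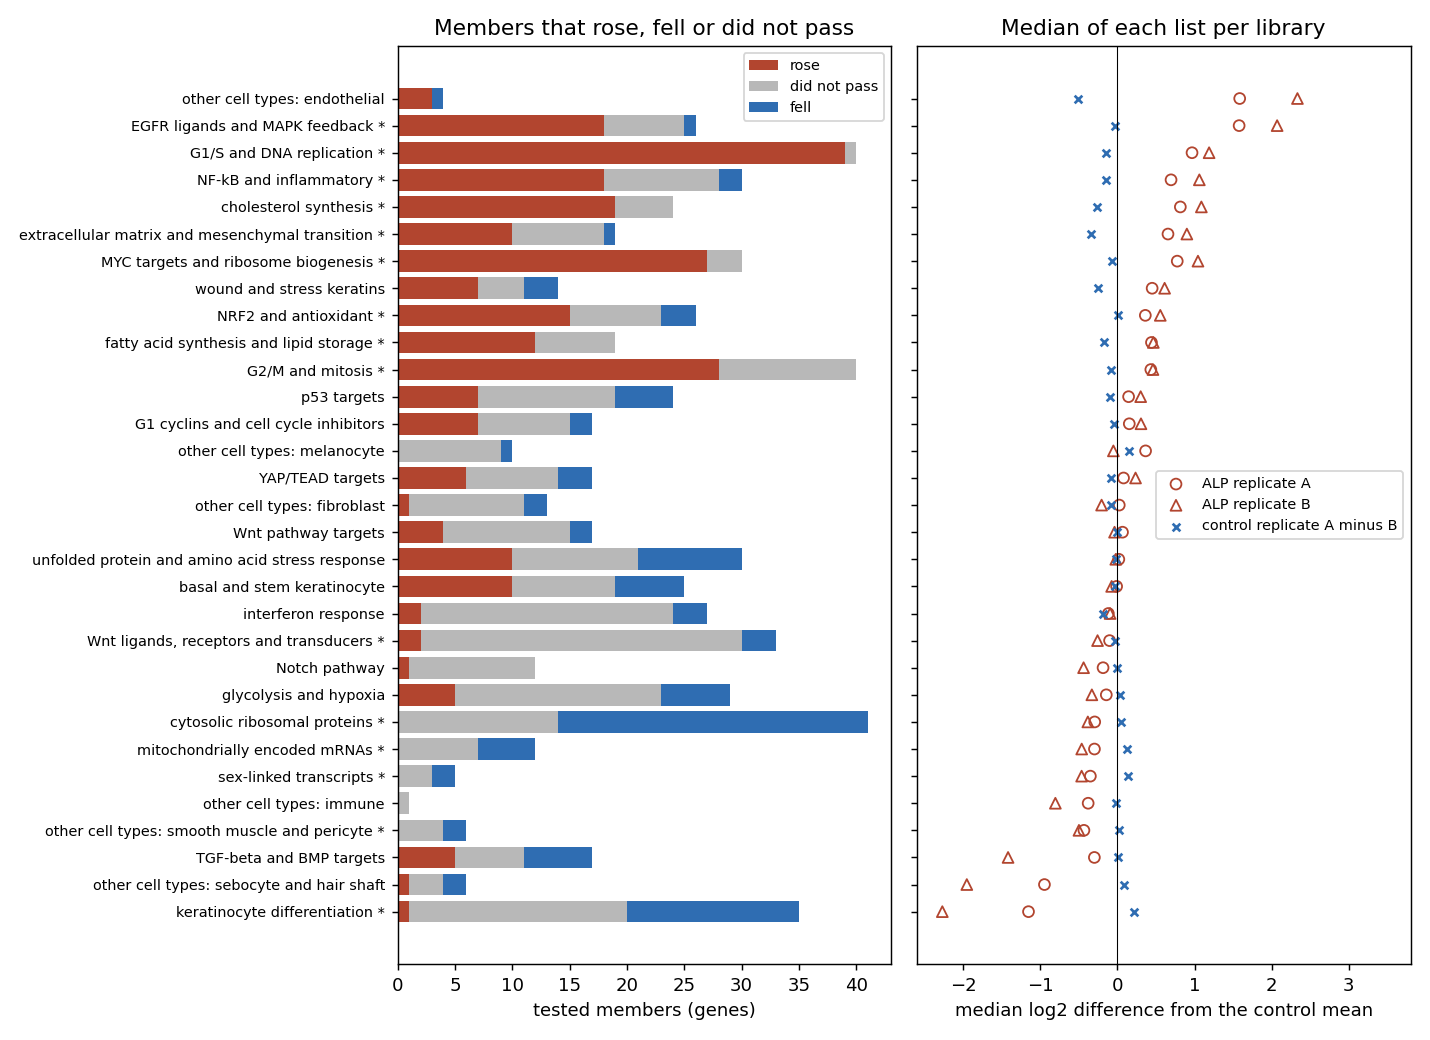
For each of the 31 gene lists, the left panel gives the number of tested members that rose, did not pass or fell, and the right panel the median log2 difference of each ALP library from the control mean, with the difference between the control libraries as blue crosses. Asterisks mark the 15 lists with a camera adjusted p under 0.05, and in keratinocyte differentiation ALP replicate A lies at -1.15 and ALP replicate B at -2.27.

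Markers of other cell types were measured as a check of the cultures. Of 18 immune genes, 1 was abundant enough to test, Cd68, at 5.99 ± 1.34 CPM in ALP and 9.19 ± 0.096 in control (adjusted p = 0.0835). The log2 difference of Cd68 was -0.87 without ALP replicate A and -0.39 without ALP replicate B. Among 13 fibroblast genes 1 rose and 2 fell by either adjustment, adjusted over the list alone included, and 2 and 2 without ALP replicate A (camera adjusted p = 0.843, direction down, median 0.10, mean -0.09). The fibroblast median was -0.26 without ALP replicate A, -0.18 without control replicate A, 0.04 without either other library and 0.03 by limma-voom. Fbn1 was up by 2.04 ± 0.29 and Postn and Dcn fell by 1.72 ± 0.25 and 2.56 ± 0.62 (Dcn -4.38 without ALP replicate A). Of 10 melanocyte genes Mitf fell by 1.27 ± 0.19 and the others did not pass, also when adjusted over the list alone, with 2 down without ALP replicate A (camera adjusted p = 0.965, direction down, median 0.18, mean 0.04). The melanocyte median was -0.14 without ALP replicate A, 0.48 without ALP replicate B, 0.42 without control replicate A, 0.27 without control replicate B and -0.33 over the 4 members with at least 10 CPM in 2 libraries. The pigment gene Tyrp1 measured 25.2 ± 0.096 CPM in ALP and 19.8 ± 1.61 in control. Of 6 smooth muscle and pericyte genes 2 fell by either adjustment, adjusted over the list alone included, Cspg4 by 1.57 ± 0.15 and Myl9 by 0.55 ± 0.14 (camera adjusted p = 0.0459, adjusted p = 0.572 with an estimated correlation, fry adjusted p = 0.0276). Myl9 did not pass by DESeq2's Wald test (adjusted p = 0.0652), which left 1 member down. Of 6 sebocyte and hair shaft genes 1 rose and 2 fell (1 and 4 adjusted over the list alone, by limma-voom and without either ALP library). The camera adjusted p was 0.177, and 0.0158 without ALP replicate B. Soat1 was up by 0.94 ± 0.17 and Dlx3 down by 1.71 ± 0.45 (-2.73 without ALP replicate A and -1.13 without ALP replicate B). The smooth muscle list lost its call without ALP replicate A (camera adjusted p = 0.0896) and without control replicate B (0.0627). Of 4 endothelial genes, too few for camera, Flt1, Kdr and Pecam1 rose by 3.50 ± 0.54, 3.46 ± 0.47 and 1.21 ± 0.32 and Tek fell by 2.63 ± 0.51, the same 3 and 1 adjusted over the list alone.

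Sex-linked transcripts showed that every library held RNA with both Xist and Y-linked mRNAs. Xist measured 383 and 392 CPM in the ALP libraries and 443 and 402 in the controls (adjusted p = 0.312), and the Y-linked Ddx3y 31.6 and 37.9 against 42.8 and 38.3 (adjusted p = 0.243). The log2 difference of Ddx3y was -0.10 without ALP replicate A and -0.35 without ALP replicate B. Of the 5 tested members 0 rose and 2 fell (0 and 3 adjusted over the list alone), Uty by 0.85 ± 0.22 and Kdm5d by 0.53 ± 0.14, the latter not by DESeq2's Wald test (adjusted p = 0.0527), with a camera adjusted p of 0.0459 and an adjusted p = 0.572 with an estimated correlation. The call of this list was lost without ALP replicate A (camera adjusted p = 0.0896) and without control replicate A (0.117).

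The authors' deposited table gave 4096 genes at an adjusted p under 0.05, 2357 higher and 1739 lower in ALP, of which 1402 changed at least 2-fold. Of the calls in the authors' deposited table, 3806 were also called here, 290 were not, and 544 genes were called here alone, with 0 of the shared calls in opposite directions. Log2 fold changes in the authors' deposited table and here had a Pearson correlation of 0.9998 across genes tested here, both being computed from the same counts. For Cxcl1 the authors' deposited table gives a log2 fold change of 5.29 with an adjusted p of 4.01e-38.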

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

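Scalings and other tests left the count of changed genes within 1.5 times the value reported, while the threshold, the lack of a filter and 3 of the 4 libraries left out did not. The count was 4325 with DESeq2 size factors, 4355 with upper-quartile scaling, 4348 with library totals, 4211 over protein-coding genes and 4188 by edgeR's earlier method, the one alternative of the fit chosen after seeing the data. In each of these at least 4037 of the 4350 calls were called again, and 0 changed sign in any setting. Without a low-count filter, which raises the genes tested to 25280, edgeR called 0 genes (7068 at an unadjusted p under 0.05). It also called 0 at an adjusted p under 0.01, and both held in each direction and at 2-fold. DESeq2's Wald test, given the same 25280 genes, called 4056. By default it drops genes of low mean count before the adjustment, so it was not an unfiltered fit. With at least 10 CPM in 2 libraries, 853 genes changed at least 2-fold, in part because 9385 genes were tested. Over the 4 fits that each left out a library, the count of changed genes ran from 0 (without either control) to 7518 (without ALP replicate A), genes higher from 0 to 3872, genes lower from 0 to 3646 and genes changed at least 2-fold from 0 to 3008, and without ALP replicate B 5073 genes changed. With a control left out the spread comes from the ALP pair alone, which differed more than the control pair, and 119 of 138 named genes then lost their call, while no named gene changed sign in any setting. Of the gene lists, 15 moved, 0 with an estimated correlation, 1 by fry and between 14 and 16 without 1 library. The direction turned, with no call, for 4 lists, and the cause was not tested. These were basal and stem keratinocyte (adjusted p = 0.705 with at least 10 CPM, and from 0.651 to 0.993 over the fits without 1 library), TGF-beta and BMP targets (0.687 with at least 10 CPM and 0.944 by fry), the unfolded protein response (0.855 to 0.990 without 1 library) and melanocyte (0.991 with library totals, 0.652 to 0.753 without 1 library). No paired analysis was possible because the columns of the groups share only 1 replicate number, and those numbers differ from the labels. At this depth and with 2 libraries per group, changes of 1.5-fold were mostly missed in counts simulated with 200 changed genes. With 4281 genes changed, nearer the 4350 called here, recovery at 2-fold was 81.4% against 69.4%, and 1.5-fold was not simulated. The share of small changes missed here is thus not known, and a gene that did not pass is not shown to be unchanged.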

Other observations

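The tests of a control share in an ALP library and of endothelial cells were chosen after the result was seen, as was the choice of transcription factors. The rule for reading the first was changed 3 times after its value was known, ending with all of 12 settings having to fall on one side, and that for the second was changed 2 times, first to add Pecam1 and Tek to a sum and then to take the median over members. Of 918 tested genes that the table assigns to a transcription factor family, 75 were higher and 176 lower in ALP. Among those passing the abundance rule, the largest increases were in Etv4 (4.21), Hmga2 (3.94), Etv5 (3.42) and Fosl1 (2.99) on the log2 scale, followed by Sox15 (2.01), E2f7 (1.97), Maff (1.71) and Bhlhe40 (1.61). Etv4, Etv5 and Fosl1 also belong to the list of MAPK feedback genes. Decreases included the bone morphogenetic protein targets Id4 (-2.11) and Smad6 (-1.97), Tbx1 (-1.96), Nfe2l3 (-1.88), Tfap2e (-1.83), the aryl hydrocarbon receptor gene Ahr (-1.76) and the glucocorticoid-induced Tsc22d3 (-1.75).

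ALP replicate B lay farther from the controls than ALP replicate A in 4003 of the 4350 called genes (92.0%), and the median absolute log2 distance over all tested genes was 0.44 against 0.30. The lower depth of ALP replicate B does not account for this, since the ratio of the distances was 1.43 with ALP replicate A thinned to the same depth and 1.44 before. One response reached to different degrees is a candidate explanation, with culture and library preparation not separated by the design, since the fold changes of the ALP libraries, each set against a different control, had a Spearman's rho of 0.812 across 14056 genes (0.817 with the controls exchanged), genes not being independent replicates. Control RNA mixed in ALP replicate A with RNA like that of ALP replicate B cannot be told apart from it. Such a mixture predicts equal control shares, and a difference of at most 0.05 was counted as equal. A made mixture with a share of 0.35 gave 0.353 and 0.35. It was made from the same libraries with counting noise alone, so that recovery was fixed in advance. The shares were 0.421 from 101 genes higher in ALP replicate B and 0.319 from 207 lower ones, a difference of 0.102 (bootstrap interval 0.0785 to 0.125, treating genes as independent), and the interval lay wholly above 0.05 in 10 of 12 settings of gene choice, control library and scaling, but the difference was 0.0388 for genes chosen at 2-fold in place of 4-fold and 0.0096 at 1.5-fold. At 3-fold it was 0.0771, so it rose with the fold used to choose genes, and the reason was not tested.

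Ribosomal protein mRNAs fell while genes that build ribosomes rose. Ribosomal protein transcripts are short, with a median of 1120 bases against 3183 for all tested genes, but among 10000 random lists matched on transcript length and expression the list's median of -0.34 lay at percentile 0.02, with a matched median of 0.08 (95% interval -0.19 to 0.24). Matched on GC content and expression it lay at percentile 0.01, the smallest the draws can give, with a matched median of 0.23 (0.01 to 0.39). The random lists were drawn gene by gene, whereas members of the list varied together (estimated correlation 0.54), so the percentiles overstate how unusual its median was. The matched medians themselves showed no fall. Length and GC bias over this range thus do not account for the fall, as far as the longest annotated transcript describes them. How closely expression was matched was not measured. The length-matched genes were somewhat longer, with a median of 1389 bases, and the transcripts sequenced may be shorter than the longest annotated. A bias confined to the shortest transcripts is therefore not excluded. Reads shared with pseudogenes were not tested and stay open beside an effect of ALP.

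Flt1 and Kdr, which encode receptors for vascular endothelial growth factor, rose by 3.50 and 3.46 on the log2 scale. Endothelial cells in the ALP cultures would bring all their abundant transcripts, yet the 8 other members of the endothelial list had a median count of 1.34% of the mean Flt1 and Kdr count in the ALP libraries (1.56% in ALP replicate A and 0.959% in ALP replicate B), and 7 of the 8 lay at 2.97% or less. Tek fell by 2.63, with only 7 counts in the ALP libraries. Cdh5, Cldn5, Emcn, Esam, Tie1 and Vwf together had 20 counts against 673 for Flt1 and Kdr, which argues against endothelial cells as the source. The exception was Pecam1, which rose by 1.21 from 70 and 97 counts in the controls and whose 357 counts in ALP bring the sum of all 8 members to 384, or 57.1% of the Flt1 and Kdr count. Expression of Flt1 and Kdr by the cultured keratinocytes may be the source, a hypothesis that bulk RNA does not test further.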
